A study of Vibrio splendidus with 10 samples.

How the data were processed

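RNA was sequenced from cultures of Vibrio splendidus strain 12B01, a marine bacterium, in 10 libraries. Per the labels, 3 libraries came from early aggregates, 3 from the shell material of late aggregates, 2 from cells released by late aggregates and 2 from planktonic cells in exponential growth. The aggregates grew on 0.07% w/v alginate, a polysaccharide of brown algae, and the planktonic cells, per their carbon source field, on 0.07% w/v alginate oligosaccharides. The growth protocol given for all 10 libraries names alginate alone, so the carbon source of the planktonic cells rests on that field, their titles and a line of their treatment protocol. Cultures were kept at 25 °C in 70 mL of minimal medium with 10 mM ammonium, and 15 mL of culture went into the RNA preparation. Per the labels' protocols, the aggregate stage was judged by microscopy, total RNA was depleted of ribosomal RNA, and libraries were made with a strand-specific Illumina kit. The molecule field of the labels reads polyA RNA for the 8 aggregate libraries and total RNA for the 2 planktonic libraries, although the extraction protocol is the same.

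The deposited values are raw read counts per gene, whole numbers with no normalization, in 1 file per library. The submitters' processing notes name Trimmomatic 0.30, FastQC 0.11.9, Bowtie2 2.3.4.1, SAMtools 1.9 and HTSeq without a version. The options of these tools, the genome build and the annotation are not given in the sources used here. The strand setting of the counting is not stated either, but all 10 deposited files carry the marker "anti" in their names, which no source explains. It can be read as a count of antisense reads, or as the setting for a kit whose reads lie opposite to the transcript. In the first case every gene level given here would be that of antisense reads. The files do not settle this, and reads of a gene and of its antisense partner cannot be told apart. Reads shared between near-identical gene copies cannot be assessed from the counts either. Each file lists 5231 genes by locus tag and protein accession, followed by 5 bins of reads that were not assigned to a gene. The bins were kept out of library sizes and tests. Between 67.2% and 91.8% of all reads of a library lay in the bin for no annotated feature, and between 5.51% and 10.2% were not aligned. Remaining ribosomal RNA, reads between genes and reads on the strand not counted would all fall in the first of these bins and cannot be told apart in the files, in which every gene has a protein accession.

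The files do not pair locus tags with gene names or product descriptions, and no genome or annotation was used here. The 25 gene lists fixed before the data were examined were defined on product descriptions, so none of them could be matched or tested. For the same reason genes are given by locus tag without a function or a genome position. The rule for named genes, also fixed before the data were examined, then allowed 2 genes that rose and 2 that fell per comparison, those with the lowest p-values. Neighbouring genes were taken as consecutive lines of the files whose protein accession numbers also follow one another, which assumes that these numbers follow the genome, and a run was a stretch of at least 4 neighbours that all passed the test in the same direction. Runs were examined only after the data were seen.

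Genes with enough reads were selected with edgeR's filterByExpr, which kept 4584 genes. The main test was edgeR's quasi-likelihood test with TMM factors, 1 mean per group over all 10 libraries and robust estimation. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 within 1 comparison, and 5 comparisons were made. Standard errors of log2 fold changes were obtained as the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM values, counts scaled here by the TMM-adjusted library size, as mean ± SD over libraries, and log2 CPM values for principal components and correlations used a prior count of 2. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9.

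The alternatives were RLE size factors, library sizes without composition factors, DESeq2, no filter on low counts, a fit of only the groups compared, the replicate number as a block, and leaving out each library of the groups compared in turn. Thinning every library to the shallowest one and leaving out genes above 2% of any library were added after seeing the data, as were overlaps at an unadjusted p under 0.05.

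The test was tried on simulated counts with 200 changed genes per comparison. All groups were simulated with the same spread per gene, whereas the real shell libraries differed more among themselves than those of other groups. The shares below therefore hold for groups of equal spread only. For shell against early, 68.8% of 4-fold changes (2 on the log2 scale) and 8.0% of 2-fold changes were recovered among 4453 genes tested. For released against early, 40.8% of changes of 2 on the log2 scale and 90.0% of changes of 4 were recovered among 4501 genes, and for released against shell 44.0% and 94.0% among 4511 genes. For early against planktonic these shares were 53.1% and 98.0% among 4484 genes, and for released against planktonic 44.0% and 98.0% among 4505 genes. False calls made up 3.25% of calls for early against planktonic, 4.35% for released against early, 5.22% for released against shell, 8.09% for shell against early and 10.2% for released against planktonic.

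Libraries within a group differed by 7.21 to 66.2 times the sampling noise in a chi-square statistic per degree of freedom, so no library was a copy of another. A floor of 3 reads corresponds to 1.52 CPM in the deepest library and 14.9 CPM in the shallowest. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. The labels name the replicates without saying that they came from separate cultures. The p-values therefore rest on the spread between these libraries, part of which may be technical. This spread was estimated per gene over all groups together, so each p-value also draws on groups not compared. The groups differed in it: the median SD of log2 CPM was 0.83 in shells, 0.39 in early aggregates, 0.24 in released cells and 0.32 in planktonic cells.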

Results

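Transcript levels were measured by RNA sequencing in Vibrio splendidus 12B01 growing as multicellular aggregates on alginate, at an early stage and after the aggregates had ruptured. The late material was separated into the shell that remained and the cells released from inside. Planktonic cells, labelled as grown on alginate oligosaccharides, were a further reference. There were 3 early, 3 shell, 2 released and 2 planktonic libraries. The strand counted is not stated, and a marker "anti" in the names of all 10 deposited files, which no source explains, leaves open that antisense reads were counted. Each level below is therefore that of reads assigned to a gene, which may be sense or antisense.

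Reads assigned to genes numbered 1766720 ± 181462 (SD, n = 3) in early libraries, 307590 ± 99463 (SD, n = 3) in shell libraries and 1507420 ± 106467 (SD, n = 2) in released libraries. The planktonic libraries held 228178 and 1508171 such reads. These reads were 21.8% ± 2.09 (SD, n = 3) of all reads for early aggregates, 3.77% ± 1.53 (SD, n = 3) for shells and 16.9% ± 3.82 (SD, n = 2) for released cells. The planktonic shares were 4.57% (95% Wilson interval 4.55 to 4.59) in replicate 1 and 15.4% (15.35 to 15.40) in replicate 2. The shell share was 18.1 percentage points below the early share, with an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries allow. The shell libraries were also dominated by fewer genes: the 10 most abundant genes of each library took 26.9% ± 10.5 (SD, n = 3) of gene reads in shells and 8.91% ± 1.25 (SD, n = 3) in early aggregates. A single gene, V12B01_12555, singled out after its values were seen, took 5.26% (95% Wilson interval 5.18 to 5.33), 9.96% (9.87 to 10.05) and 20.6% (20.4 to 20.7) of gene reads in shell replicates 1, 2 and 3, and 3.67% and 2.81% in released replicates 1 and 2.

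**Figure D1:**
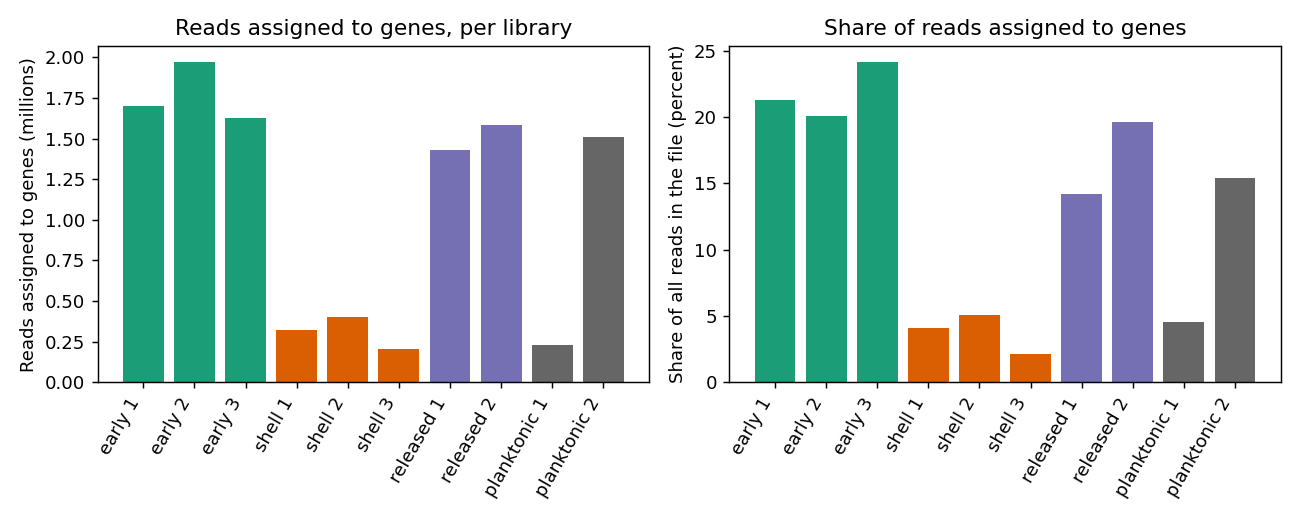
Bars give, for each library, the number of reads assigned to genes (left) and their share of all reads in percent (right), coloured by group; there is 1 bar per library and no error bar. The 3 shell libraries and planktonic replicate 1 lie at 201732 to 399100 reads and 2.09% to 5.10%, below every other library.

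Log2 CPM values correlated more closely between released and early libraries than between shell and early libraries. Across the 4584 genes tested, log2 CPM of released and early libraries correlated with a mean Pearson r of 0.87 over 6 library pairs (0.86 to 0.87). Shell and early libraries correlated with a mean r of 0.72 over 9 pairs (0.65 to 0.77), and shell and released libraries with 0.73 over 6 pairs (0.68 to 0.77). Shell libraries had their highest mean r with planktonic libraries, 0.77 over 6 pairs (0.73 to 0.81). Planktonic libraries correlated with early ones at a mean r of 0.785 over 6 pairs (0.72 to 0.84). With released libraries it was 0.78 over 4 pairs (0.74 to 0.82). Genes were not tested between shells and planktonic cells. These are correlations across genes, which are not independent replicates, and the fewer reads of the shell libraries lower them by counting noise; the differences between these correlations were not tested. Shell replicates also differed most among themselves, with r of 0.76 to 0.82, against 0.92 to 0.97 among early replicates, 0.96 between the released libraries and 0.91 between the planktonic libraries. The first principal component held 36.6% of the variance and placed the shell and planktonic libraries apart from the early and released ones. Libraries with a lower share of reads assigned to genes mostly lay higher on it, from early replicate 3 (-58.0, share 24.1%) to shell replicate 3 (59.5, share 2.09%). Planktonic replicate 2 (10.2, 15.4%) and released replicate 1 (-32.3, 14.2%) went the other way. Group and assigned share are thus largely mixed along this component.

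**Figure D2:**
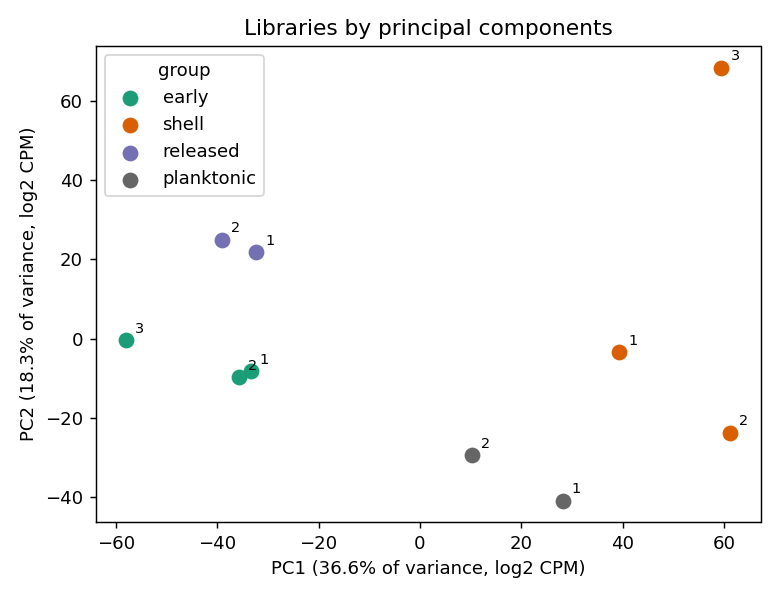
Each point is 1 library placed by the first (x, 36.6% of variance) and second (y, 18.3%) principal component of log2 CPM, coloured by group and numbered by replicate. Early and released libraries lie at negative values of the first component, while shell and planktonic libraries lie at positive values.

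The comparison of shell with early aggregates asked which genes differ between the structure left after rupture and the young aggregate. In shells 661 genes rose and 621 fell, together 1282 of 4584 tested. The median change was 2.20 on the log2 scale for genes that rose and -1.92 for genes that fell. V12B01_11555 rose 41.9-fold, from 7.86 ± 3.24 to 342 ± 103 CPM (SD, n = 3 each), a log2 fold change of 5.39 with SE 0.44. V12B01_00607 rose 26.1-fold, from 6.55 ± 2.08 to 177 ± 22.5 CPM, a log2 fold change of 4.71 with SE 0.43. V12B01_02580 was 13.9-fold lower in shells, at 321 ± 144 against 4426 ± 907 CPM, a log2 fold change of -3.80 with SE 0.48. V12B01_05425 was 9.08-fold lower, at 27.9 ± 12.3 against 236 ± 22.6 CPM, with 6 to 8 reads per shell library and a log2 fold change of -3.18 with SE 0.40. The adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 2.17e-05 for V12B01_11555, 4.6e-05 for V12B01_00607 and 0.000185 for V12B01_02580 and V12B01_05425.

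Many genes that changed in shells lay side by side. There were 36 runs of at least 4 neighbouring genes called in the same direction, 17 of genes that rose and 19 of genes that fell, with 216 genes in all. Shuffling the calls over the tested genes gave 2.31 such runs on average and at most 10 in 1000 shuffles. V12B01_05425 belonged to a run of 9 genes that all fell, with a median log2 fold change of -2.53, and V12B01_02580 to a run of 5 genes that all fell, with a median of -2.48. The longest run, chosen after its values were seen, held the 17 genes from V12B01_22436 to V12B01_22516. All of them rose in shells, by 3.06 to 5.70 on the log2 scale, with edgeR adjusted p between 9.63e-05 and 0.0215. Their summed level was 17551 ± 9942 CPM in shells (SD, n = 3) and 1062 ± 489 CPM in early aggregates (SD, n = 3). In released cells, at 1143 ± 197 CPM (SD, n = 2), 0 of the 17 passed against early aggregates by edgeR's adjusted test, by its unadjusted p or by DESeq2. Planktonic cells lay between these groups and the shells, at 2540 ± 10.7 CPM (SD, n = 2). Against planktonic cells, 3 of the 17 were lower in early aggregates and 0 passed in released cells by edgeR's adjusted test.

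**Figure D3:**
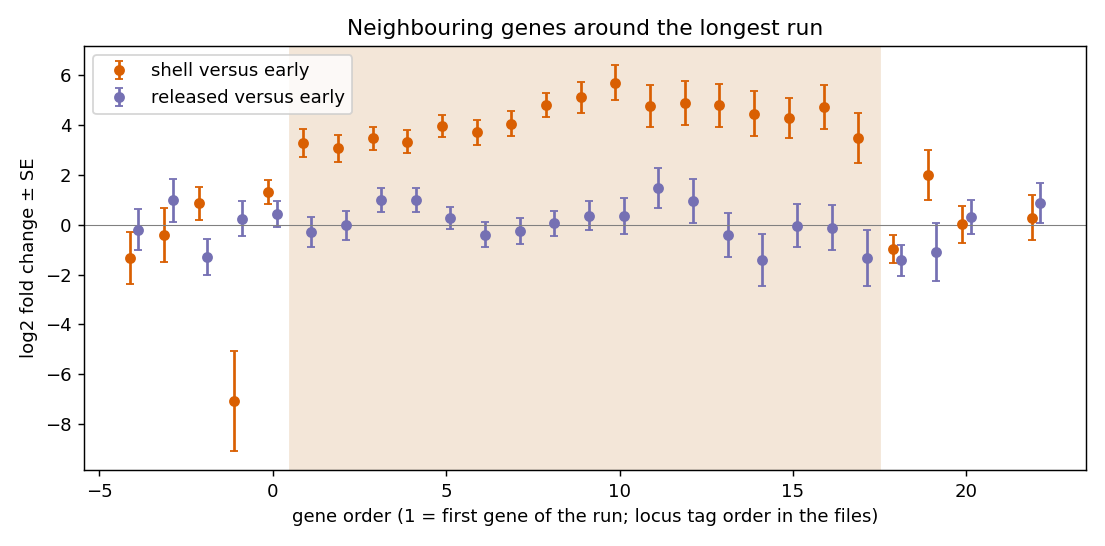
Points give the log2 fold change (y) with its standard error for shell against early (orange) and released against early (purple) aggregates, by the order of genes in the files (x), with the 17 genes of the run shaded. In the shaded run the shell values lie between 3.06 and 5.70 and the released values between -1.43 and 1.47.

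The balance of rising and falling genes in shells depended on scaling: 51.6% of the changed genes rose with TMM factors and 37.3% with library sizes alone, where the median log2 fold change of all genes moved from -0.12 to -0.35. The lower share of reads assigned to genes, given above, separated the shell from the early libraries completely.

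The comparison of released cells with early aggregates asked what differs between cells set free at rupture and the young aggregate. In released cells 164 genes rose and 96 fell, together 260 of 4584. The median change was 2.88 on the log2 scale for genes that rose and -2.22 for those that fell. V12B01_11520 rose 46.2-fold, from 5.35 ± 1.63 (SD, n = 3) to 247 ± 60.2 CPM (SD, n = 2), a log2 fold change of 5.53 with SE 0.51. V12B01_25139 rose 131-fold, from 5.39 ± 3.74 to 727 ± 424 CPM, with 4 to 18 reads per early library and a log2 fold change of 7.03 with SE 0.66. V12B01_18011 was 29.0-fold lower in released cells, at 2.38 ± 1.41 against 72.5 ± 18.6 CPM, with 2 and 5 reads in the released libraries and a log2 fold change of -4.86 with SE 0.62. V12B01_16911 was 10.0-fold lower, at 17.5 ± 3.71 against 176 ± 68.6 CPM, a log2 fold change of -3.32 with SE 0.50. The edgeR quasi-likelihood adjusted p was 6.02e-05 for both genes that rose, 0.000587 for V12B01_18011 and 0.00149 for V12B01_16911. V12B01_11520 stood in a stretch of 3 neighbouring genes that all rose, with a median log2 fold change of 4.30. Its rise was not particular to released cells: in shells its log2 fold change against early aggregates was 4.57 with SE 0.50. Between released cells and shells it did not pass, with an edgeR adjusted p of 0.139. There were 7 runs of at least 4 neighbours, 4 of genes that rose and 3 of genes that fell, against at most 1 in 1000 shuffles.

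This count rested on few libraries. It was 149 without early replicate 1, 121 without early replicate 2, 84 without released replicate 1 (75 higher and 9 lower) and 45 without released replicate 2 (43 higher and 2 lower), where the remaining released library was assumed to vary like the other groups. DESeq2 gave 457 genes, 230 higher and 227 lower, and a fit of only these groups 522, 278 higher and 244 lower. The replicate number as a block gave 403, 245 higher and 158 lower. The balance of rising and falling genes thus also depended on the method. The log2 fold change of V12B01_25139 was 6.27 without released replicate 2, 7.67 without early replicate 1 and 5.85 after thinning to equal depth. That of V12B01_18011 was -5.60 without released replicate 2 and -4.26 after thinning, and that of V12B01_16911 was -4.03 after thinning. V12B01_16911 missed the threshold without released replicate 2, with an edgeR adjusted p of 0.057, the highest over its 13 alternatives (lowest 2.08e-08).

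Some genes were called in the same direction in both late groups against early aggregates. In both, 87 genes rose and 56 fell, together 143 of the 260 genes changed in released cells and of the 1282 changed in shells. Independent lists of these sizes would share 36.7 genes, but both comparisons use the same 3 early libraries, and part of the excess may come from these shared controls. In 20 simulations of unchanged groups against the same controls 0 genes were shared by edgeR's adjusted test, which calls almost nothing there and so gives no reference for lists of this size. At an unadjusted p under 0.05, a threshold added after seeing the data, the simulated groups gave lists of 207.5 and 206 genes on average that shared 33.5, where independent lists would share 4.80, so the shared controls alone raise an overlap. The real lists at that threshold, of 1819 and 851 genes, shared 394, where independent lists would share 169; as they are much longer, the simulated excess cannot be set against theirs. The shared count was 75 without early replicate 2, 50 without released replicate 1 (43 higher and 7 lower), 36 without released replicate 2 (35 higher and 1 lower) and 235 with DESeq2 (115 higher and 120 lower), and library sizes alone gave 70 higher and 75 lower. A further 8 genes changed in opposite directions: 7 fell in shells and rose in released cells and 1 did the reverse. The 143 genes included V12B01_11555, V12B01_02580 and V12B01_05425, named above for shells. They also included V12B01_11520, V12B01_18011 and V12B01_16911, named above for released cells. Against early aggregates, V12B01_00607 passed in shells alone and V12B01_25139 in released cells alone.

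**Figure D4:**
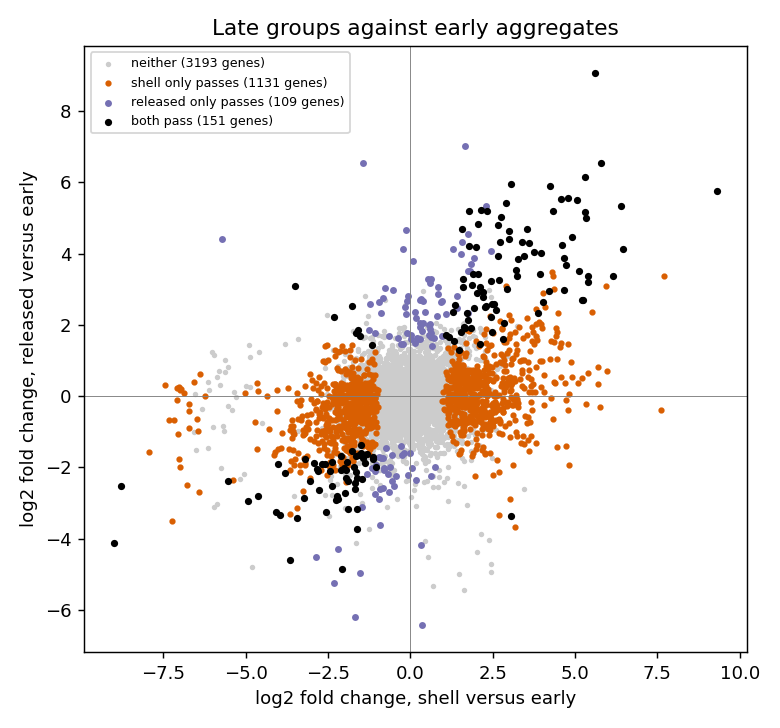
Each point is 1 of 4584 genes, with its log2 fold change in shell (x) and in released cells (y), both against early aggregates, coloured by which comparison passed an adjusted p of 0.05. The 1131 genes called in shells alone spread along the x axis, and the 151 genes called in both lie mainly in the quadrants of equal sign.

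The comparison of released cells with shells asked which genes differ between the parts of the ruptured aggregate. The share of reads assigned to genes separated these groups completely too, at 2.09% to 5.10% in shells and 14.2% to 19.6% in released libraries. Its part in the differences below cannot be told apart from that of the material. In released cells 474 genes were higher and 515 lower than in shells, together 989 of 4584. V12B01_21801 was 15.7-fold higher, at 1313 ± 39.1 (SD, n = 2) against 84.2 ± 33.7 CPM (SD, n = 3), a log2 fold change of 3.97 with SE 0.46. V12B01_25139, also higher against early aggregates, was 41.3-fold higher than in shells, where it reached 15.0 ± 13.1 CPM with 0 to 8 reads per library, a log2 fold change of 5.37 with SE 0.66. V12B01_11385 was 85.2-fold lower, at 3.42 ± 0.906 CPM with 4 and 6 reads against 297 ± 158 CPM, a log2 fold change of -6.41 with SE 0.72. V12B01_00607 was 20.3-fold lower, at 8.56 ± 0.329 against 177 ± 22.5 CPM, a log2 fold change of -4.35 with SE 0.50. The edgeR quasi-likelihood adjusted p was 0.000766 for V12B01_25139 and 0.000682 for the other genes. V12B01_11385 belonged to a run of 10 neighbouring genes that were all lower in released cells, with a median log2 fold change of -4.77, and V12B01_21801 to a run of 4 that were all higher, with a median of 3.01. The 17 genes of the longest run, chosen for their rise in the same shell libraries, were all lower in released cells than in shells, with a median of -4.31. There were 13 runs in all, against at most 5 in 1000 shuffles.

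Of the genes changed in shells against early aggregates, 651 differed from released cells in the same direction, 384 higher in shells and 267 lower, where independent lists would share 138. Of the genes changed in released cells against early aggregates, 94 differed from shells in the same direction, against 27.7 for independent lists. Each of these pairs of comparisons shares the libraries of the group it is about, so overlap in this direction is in part built in: in simulated unchanged groups at an unadjusted p under 0.05, 49.2 and 53.3 genes were shared, where independent lists would share 4.93 and 4.82. Simulated lists are shorter than the real ones, so this excess gives no reference for the 651 and 94. With the replicate number as a block, the count of 94 became 202 (143 higher and 59 lower). The count of 651 was 399 without shell replicate 2, 250 without released replicate 1 (110 higher and 140 lower), 40 without released replicate 2 and 317 in fits of only the groups compared, and library sizes alone gave 276 higher and 403 lower. The count of 94 was 46 without early replicate 1, 44 without early replicate 2, 142 without shell replicate 1, 30 without released replicate 1, 4 without released replicate 2, 169 with DESeq2 and 62 after thinning to equal depth.

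The count of 989 was 630 without shell replicate 2, 338 without released replicate 1 (210 higher and 128 lower), 50 without released replicate 2 (29 higher and 21 lower) and 439 in a fit of only these groups (156 higher and 283 lower), and 47.9% of the changed genes were higher with TMM factors but 60.7% with library sizes alone, where the median of all genes moved from 0.10 to 0.26. The log2 fold change of V12B01_25139 was 4.62 without released replicate 2, and that of V12B01_00607 was -3.74 after thinning.

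Early aggregates were next compared with planktonic cells, which per their carbon source field grew on oligosaccharides of alginate, although the growth protocol of the labels names alginate for them too. In early aggregates 340 genes were higher and 257 lower, together 597 of 4584. V12B01_16716 was 40.1-fold higher, at 618 ± 109 (SD, n = 3) against 14.8 ± 2.26 CPM (SD, n = 2), with 4 and 30 reads in the planktonic libraries and a log2 fold change of 5.33 with SE 0.49. V12B01_24289 was 58.2-fold higher, at 525 ± 158 against 8.20 ± 2.29 CPM, a log2 fold change of 5.86 with SE 0.61. It had 2 and 18 reads in planktonic replicates 1 and 2, the first below the floor of 3 reads. It belonged to a run of 6 neighbouring genes that were all higher, with a median of 4.62. The neighbours V12B01_11725 and V12B01_11730 were 41.6-fold and 29.6-fold lower in early aggregates. V12B01_11725 reached 21.1 ± 3.19 against 878 ± 259.5 CPM and V12B01_11730 reached 32.0 ± 6.27 against 948 ± 55.7 CPM, with log2 fold changes of -5.38 (SE 0.50) and -4.89 (SE 0.48). The edgeR quasi-likelihood adjusted p was 5.49e-05 for V12B01_16716 and V12B01_11725, 6.8e-05 for V12B01_24289 and 5.79e-05 for V12B01_11730. Both of the higher genes were lower in shells than in early aggregates, with log2 fold changes of -2.42 (SE 0.36) for V12B01_16716 and -2.52 (SE 0.42) for V12B01_24289. The edgeR adjusted p was 0.000449 and 0.00101. These genes were chosen for being high in the same early libraries, so a fall against these libraries is in part built in and these p-values are no independent evidence.

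Released cells were compared with planktonic cells as 2 kinds of free cells with different histories. In released cells 343 genes were higher and 218 lower, together 561 of 4584. V12B01_16716, also higher in early aggregates against the same planktonic libraries, was 20.6-fold higher in released cells, at 317 ± 57.7 CPM (SD, n = 2), a log2 fold change of 4.36 with SE 0.49. V12B01_24894 was 24.5-fold higher, at 378 ± 123 against 14.8 ± 2.26 CPM (SD, n = 2 each), with 4 and 30 reads in the planktonic libraries and a log2 fold change of 4.61 with SE 0.53. V12B01_11165 was 16.1-fold lower, at 319 ± 71.2 against 5141 ± 739 CPM, a log2 fold change of -4.01 with SE 0.52. V12B01_01387 was 71.4-fold lower, at 2.76 ± 1.99 CPM with 2 and 6 reads in the released libraries, a log2 fold change of -6.16 with SE 0.81. The edgeR quasi-likelihood adjusted p was 0.000765 for each of these genes.

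In both comparisons with planktonic cells, carbon source, growth as aggregates and the molecule field of the labels differ together and cannot be separated. Growth stage may differ too, as only the planktonic cells are labelled as exponential. The planktonic samples also bear sample numbers from a block apart from that of the aggregates. A difference in preparation or sequencing batch can therefore not be separated either. The count of 597 for early aggregates was 378, 363 and 379 without early replicates 1, 2 and 3, 119 without planktonic replicate 1 (53 higher and 66 lower), 170 without planktonic replicate 2 and 896 in a fit of only these groups. The count of 561 for released cells was 212 without released replicate 1 (159 higher and 53 lower), 190 without released replicate 2 (155 higher and 35 lower), 106 without planktonic replicate 1 (55 higher and 51 lower), 159 without planktonic replicate 2 (99 higher and 60 lower), 882 with DESeq2 and 1467 in a fit of only these groups. With library sizes alone, the share of changed genes that were higher fell from 57.0% to 37.1% for early aggregates and from 61.1% to 38.7% for released cells, and the medians of all genes moved from 0.08 to -0.23 and from 0.05 to -0.33. The log2 fold change of V12B01_01387 was -7.17 without released replicate 1, -5.57 without released replicate 2, -5.38 without planktonic replicate 2 and -5.17 after thinning.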

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

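Among the tests in this part, thinning to equal depth and leaving out abundant genes were chosen after the data were seen. A difference between the late groups was found for 8 genes that changed in opposite directions in shells and in released cells against early aggregates. They were few beside the 143 genes called in the same direction in both. All 8 genes with opposite changes also passed between released cells and shells in edgeR's test, but that difference is the sum of the opposite changes they were selected for, so it is no independent evidence.

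A signal outside the counted genes was higher in 3 of 3 shell libraries than in the early libraries, by 19.4 percentage points on average, with an exact two-sided permutation p of 0.1, the smallest this design allows. Reads in no annotated gene made up 88.8% ± 3.12 (SD, n = 3) of shell reads, 69.4% ± 1.96 (SD, n = 3) of early reads, 75.2% ± 4.40 (SD, n = 2) of released reads and 83.8% ± 7.47 (SD, n = 2) of planktonic reads.

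The 1282 genes changed between shells and early aggregates were weighed against this difference in assigned reads, against depth and against a few dominant genes. After thinning all libraries to 201732 gene reads, 69.7% of the changed genes were still called with the same sign, and without the 6 genes above 2% of any library 95.3% of the others were, so neither depth nor dominant genes account for the whole pattern. The low share of assigned reads stays open, because the only other library with a low share is planktonic replicate 1: its log2 difference from planktonic replicate 2 followed the shell against early change with a Pearson r of 0.24 across 3530 genes (block-bootstrap SE 0.02), between the bounds set before the test, and with an r of 0.39 and the same sign in 62.9% among 1149 changed genes, although its changes were smaller there, with a median size of 0.38 against 1.95 on the log2 scale (slope 0.12 over the 3530 genes). The real split of the 6 libraries gave 855 changed genes in a fit of these libraries alone and the highest of the other splits 0 by edgeR's adjusted test (47 to 160 genes at an unadjusted p under 0.05), and the 10 splits, of which 1 reached the real count, are too few for a share under 0.05. A biological difference between shell and early cells remains an untested explanation.

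Early replicate 3 stood apart from the other early libraries, with a mean r to them that was 0.06 below their own r over 3530 genes. The gap was 0.054 after thinning to equal depth. This test could hardly have closed it, as the depths were close: 1626742 gene reads in early replicate 3, and 1701671 and 1971736 in replicates 1 and 2. Early replicate 3 also had the highest share of reads assigned to genes, 24.1%, against 21.2% and 20.1% in replicates 1 and 2. The part of this share in the gap was not tested. A candidate explanation is that early replicate 3 was part of the way to the released state: its log2 difference from early replicate 1 followed the difference of released cells from early replicate 2 with a Pearson r of 0.21 across genes (block-bootstrap SE 0.03), between the bounds set before the test, which leaves the question open. The same difference ran against that of shells from early replicate 2, with an r of -0.30 (SE 0.03).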

How the results depend on the processing

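The count for shell against early stayed within 1.5 times of 1282 under all 14 alternatives. These included RLE factors, library sizes alone, DESeq2, no filter, the replicate block (1339) and each left-out early or shell library (868 to 1317). The lowest count, 855 in a fit of only the groups compared, lay at the edge of this bound, with 347 genes lower against 621 in the main analysis. The genes called were less stable: that fit kept 66.5% of the main calls, and the fit without early replicate 3 kept 65.7%. Other counts moved by more than this factor under some settings, and the cause was not tested. Thinning to equal depth and leaving out abundant genes were chosen after the data were seen. DESeq2 gave 457 genes for released against early (260 in the main analysis), 882 for released against planktonic (561) and 235 for both late groups (143). A fit of only the groups compared, which estimates the spread from those groups alone, gave 522 for released against early and 439 for released against shell (989). It gave 896 for early against planktonic (597) and 1467 for released against planktonic. Both comparisons with shells thus gave fewer genes in such fits, and the comparisons without shells gave more. Shells had the largest spread between libraries, with a median SD of log2 CPM of 0.83. Shell against early gave more genes than released against planktonic in the main analysis (1282 and 561) but fewer in these fits (855 and 1467). The counts therefore do not rank the comparisons by how far the groups differ. With the replicate number as a block, released against early gave 403 genes. The count of genes setting released cells apart from both other groups went from 94 to 202, while the other counts moved by less than 1.5 times. No label says that equal numbers mark a shared flask or day, so the numbers were not treated as pairs. The deviations of same-numbered libraries from their group means correlated above 0.1 in 3 of 13 pairs (-0.10 to 0.20). Of 10 libraries, 5 correlated best with a library of their own number. In a group of 2 libraries these deviations mirror each other, so the 13 pairs are not independent and cannot decide for or against pairing. Leaving out 1 library gave 45 to 248 genes for released against early, 50 to 1174 for released against shell, 119 to 379 for early against planktonic, 106 to 212 for released against planktonic and 36 to 183 for both late groups; the lowest values followed the loss of released replicate 2 or planktonic replicate 1, which left 1 library in its group, assumed to vary like the other groups. Thinning to equal depth gave 966 genes for shell against early and 176 for released against early from 3196 genes tested. Of 260 values of named genes under the alternatives, 259 kept direction and threshold, 1 missed the threshold and 0 reversed. These genes were chosen for the lowest p-values in the same libraries, so this stability is in part built in and does not extend to other calls. Without early replicate 2, for example, 45.8% of the main calls for released against early were kept. The gene list tests were not run because no product descriptions were paired with the genes, and leaving out ribosomal and transfer RNA was not run because every gene in the files has a protein accession. Depth limits what can be seen of genes with few reads: a floor of 3 reads is 7.52 to 14.9 CPM in shell libraries, 13.1 CPM in planktonic replicate 1 and 1.52 to 2.09 CPM in the other libraries.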

Other observations

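The runs described in this part were chosen after their values were seen, and the test of neighbouring pairs was set before its result. Comparisons that share a group use the same libraries of it, so agreement or reversal of a run between such comparisons is in part built in. A run of 7 neighbouring genes, from V12B01_24244 to V12B01_24274, was higher in early aggregates and released cells than in planktonic cells and lower in shells than in early aggregates. Its summed level was 18150 ± 9102 CPM in early aggregates (SD, n = 3), 8615 ± 3021 CPM in released cells (SD, n = 2), 1562 ± 1371 CPM in shells (SD, n = 3) and 230 ± 3.71 CPM in planktonic cells (SD, n = 2). All 7 genes were higher in early aggregates than in planktonic cells, with a median log2 fold change of 5.86, and all 7 were higher in released than in planktonic cells, with a median of 4.66. All 7 fell in shells against early aggregates, with a median of -3.57, and 5 of 7 were higher in released cells than in shells, with a median of 2.52. Against early aggregates, 0 of 7 passed in released cells by edgeR's adjusted test or by DESeq2, 3 had an unadjusted p under 0.05, and the median was -1.07.

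The longest runs against planktonic cells were longer still. They were chosen for their difference between the early and planktonic libraries. The comparison of released with planktonic cells uses the same planktonic libraries, and that of shells with early aggregates the same early libraries. The 20 genes from V12B01_01407 to V12B01_01502 were all higher in early aggregates, with a median log2 fold change of 2.54, and 13 of them were also higher in released cells. Their summed level was 44240 ± 20342 CPM in early aggregates (SD, n = 3), 38791 ± 7002 CPM in released cells (SD, n = 2), 27617 ± 4468 CPM in shells (SD, n = 3) and 7526 ± 68.7 CPM in planktonic cells (SD, n = 2). In shells 4 of the 20 were lower than in early aggregates, and in released cells 0 passed against early aggregates by edgeR's adjusted test, 5 at an unadjusted p under 0.05 and 4 by DESeq2. The 19 genes from V12B01_10670 to V12B01_10760 were all lower in early aggregates than in planktonic cells, with a median of -3.30, and 15 of them were lower in released cells. In shells 10 of these 19 rose against early aggregates, and their summed level was 1065 ± 511 CPM there (SD, n = 3), against 255 ± 19.7 CPM in early aggregates (SD, n = 3), 341 ± 66.9 CPM in released cells (SD, n = 2) and 2737 ± 356.5 CPM in planktonic cells (SD, n = 2).

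Whether changed genes lie at random along the genome was tested on 4153 pairs of neighbouring genes. Both genes of a pair were called in the same direction in 10.5% of pairs for shell against early, 1.71% for released against early and 5.97% for released against shell. Shuffling the calls 10000 times gave averages of 3.91%, 0.17% and 2.33%, and the permutation p was 0.0001 in each comparison, the smallest these shuffles can give. Pairs called in opposite directions made up 1.78%, 0.02% and 1.23%. The clustering is consistent with genes transcribed together, as a hypothesis, but strand and gene borders were not used here, so shared transcripts and reads that span neighbouring genes were not separated.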
